A study of Homo sapiens with 2 samples.

How the data were processed

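Gene expression was measured in U2OS cells, a human osteosarcoma cell line, on 2 Illumina bead arrays. According to the labels, cells were plated 24 h before the exposure. They were then kept for 24 h at 37 °C either in 95% air with 5% CO2 (called untreated here) or in a chamber at 0.2% O2 with 5% CO2 (called hypoxia here). Total RNA was extracted with a column kit and labelled as biotinylated cRNA by the manufacturer's standard protocol. Each group held 1 array, and the group of each array was taken from its source label.

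The authors deposited a table that was not normalized, with the mean bead signal of each probe as an intensity on the linear scale, per the file headers. All intensities in it were positive, with a lowest value of 24.8, and no background subtraction was visible. The same deposited table held a detection p-value for each probe and array, per the file headers, which ranks the probe's signal among negative control beads. A separate deposited value table from the authors held intensities on the linear scale after a normalization between arrays. Its sorted columns differed by at most 0.237, as after quantile normalization, and each column kept the rank order of its own array. The sorted values were 1.23 times, in the median, the mean of the sorted signals of the 2 arrays. BeadStudio 3.1.3.0 is named in the submitters' processing notes. Further details of the authors' normalization, and a genome build, are not given in the sources used here.

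Each array held 48803 probes. The signals summed to 11025060 with a median of 41.2 on the untreated array, and to 11244303 with a median of 42.0 on the hypoxia array. A probe was called detected at a detection p under 0.01, which held for 13267 probes (27.2%) on the untreated array and 13751 probes (28.2%) on the hypoxia array. The number of arrays limits the precision of every value. There were no replicates, so no test between the groups, no p-value and no standard error is given, and nothing in the labels tells the culture, the array and the treatment apart. The only spread at hand was technical. In 2130 genes with at least 2 detected probes, the differences of the brightest and next brightest probe gave a standard deviation of 0.20 on the log2 scale for a single probe, called the between-probe SD here.

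The non-normalized intensities were processed with limma 3.58.1 in R 4.3.3. Background was corrected with the normexp model, with negative control parameters inferred from the detection p-values. An offset of 16 was added, the arrays were quantile normalized and log2 was taken (function neqc). Later steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. Probes were named from a platform annotation table that listed 27591 of the 48803 probes. Of these, 27578 had 1 gene and 13 had several, and the remaining 21212 probes were left unnamed. Symbols were matched by gene identifier for 27541 probes against RefSeq genes of GRCh38.p14, which was used for names only, and 18665 genes were named. Genes missing from that table, among them some members of the lists below, were not analysed here, and no coordinates are given.

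A gene was represented by its probe with the highest mean log2 level among probes detected on at least 1 array, which left 9558 genes. Differences are hypoxia minus untreated on the log2 scale. A gene detected on 1 array only was given a bound. Its brighter value was set against the higher of 2 values, the lowest normalized signal among detected probes of the other array (log2 5.52 for untreated, 5.40 for hypoxia) and the probe's own signal there. Such bounds are written as "at least". They hold on the background-corrected scale, and without background correction they are smaller. Genes were counted as higher or lower at a difference, or bound, of 2-fold. Named genes followed a fixed rule. It took the 12 largest and 12 smallest differences among genes detected on both arrays, a set of G2 regulators, up to 4 members with the largest differences of each other list, and the 5 largest bounds among genes detected on 1 array only in each direction. Genes without a usual symbol were passed over.

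A total of 27 gene lists were fixed, covering cell cycle, DNA repair, hypoxia response, metabolism, protein folding, ribosomes and markers of other cell types. The median difference of each list was placed among the medians of 10000 random lists of equal size, matched on mean level in 20 bins. These medians used the plain difference of every member, also for genes detected on 1 array only, unless bounds are named. The percentile describes these arrays and is not a test, since genes are not replicates. Gene lists, size rules, named genes and the alternatives below were chosen before the data were examined. The alternatives were median centring in place of quantile normalization, no background correction, offsets of 50 and 1, detection on both arrays, a detection p under 0.05, no detection filter, the mean over a gene's probes, the authors' value table, and random lists not matched on level.

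The steps after normalization were tested on simulated log2 levels for the comparison of hypoxia with untreated, with 9503 genes. Noise had the same SD of 0.2 at every level, and no array or culture effect was simulated. Single genes were scored only if detected on both simulated arrays, so the bounds were not tested. Of the scored genes with a log2 change of 1.5, 97.4% of 38 were counted as at least 2-fold higher. All of the 40 scored genes at -1.5, the 32 at 3 and the 38 at -3 were counted in their direction. Of 8755 other scored genes, all unchanged apart from members of the lowered list named next, 0.0114% passed 2-fold. That share does not measure the error of the counts reported below, which include bounds and any effect of array or culture. A list of 30 genes lowered by 0.3 was placed at percentile 0, and 6% of 200 unchanged lists lay outside the central 95%.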

Results

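The series asked how hypoxia alters regulators of the G2 checkpoint, the control point that holds cells with damaged or incompletely replicated DNA before mitosis. One comparison follows from its design, that of U2OS cells kept at 0.2% O2 for 24 h with untreated cells, with 1 array in each group. Both arrays had similar signals, with medians of 41.2 (untreated) and 42.0 (hypoxia) and 13267 and 13751 detected probes. Across the 12838 probes detected on both arrays, the log2 levels had a Pearson correlation of 0.969, computed across probes, which are not independent replicates. No replicates were available, so all differences below describe these arrays.

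Of the measured core targets of the hypoxia response 26 of 28, and of the glycolytic genes 11 of 16, were at least 2-fold higher on the hypoxia array, while most G2 checkpoint, mitosis, replication and DNA repair genes were lower by less than 2-fold. Of 9558 measured genes, 295 were at least 2-fold higher and 63 at least 2-fold lower in hypoxia, and 96.3% lay within 2-fold. Those counts include 51 higher and 6 lower genes that were detected on 1 array only and passed 2-fold by their bound, of which 25 and 3 did so without background correction. The median difference over all genes was -0.06. The count of lower genes depended on the processing, from 30 without background correction to 124 with an offset of 1.

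The G2 checkpoint list was lower in hypoxia as a group but by little. Of 27 measured members, 23 were below 0 and 4 above, none reached 2-fold, and the median was -0.28 (1.21-fold lower), at percentile 0.24 of matched random lists. Cyclin B1 (CCNB1), the partner of CDK1 that drives entry into mitosis, had the lowest difference of the list, from a log2 level of 9.21 to 8.33 (-0.88, 1.84-fold lower, probe ILMN_1712803). PLK1, a kinase that promotes mitotic entry and checkpoint recovery, was 1.64-fold lower (-0.71). The checkpoint kinases CHEK2 and CHEK1, which act downstream of ATM and ATR, had differences of -0.61 and -0.39, and both probes of CHEK2 gave values between -0.64 and -0.61. AURKA, an activator of PLK1, stood at -0.57, TIPIN at -0.49, ATRIP at -0.45 and TIMELESS at -0.39. TIPIN and TIMELESS protect replication forks and ATRIP is the partner of ATR. These 4 genes were named after their values were seen.

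Other G2 regulators differed by less. The phosphatases that activate CDK1 had differences of -0.41 (CDC25C), -0.28 (CDC25A) and -0.28 (CDC25B), although the 3 probes of CDC25C ranged from -0.41 to 0.03. Cyclin A2 (CCNA2) had a difference of -0.29 and CLSPN, an adaptor for CHEK1 activation, one of -0.24. FOXM1, a transcription factor of G2 genes, was at -0.12, with probes from -0.12 to 0.01. The kinase WEE1, which inhibits CDK1, had the highest difference of the list at 0.34 (1.27-fold higher). PKMYT1, another inhibitory kinase of CDK1, was at -0.11 and CDK1 itself at 0.04, but their probes disagreed in sign, from -0.11 to 0.18 and from -0.30 to 0.04. With the mean over probes, CDK1 stood at -0.13 and PKMYT1 at 0.03, so no direction is given for either. ATR was not well above background on either array. Only 7 of the 27 members were lower by more than 2 between-probe SDs (0.40), and none was higher by that much.

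**Figure D1:**
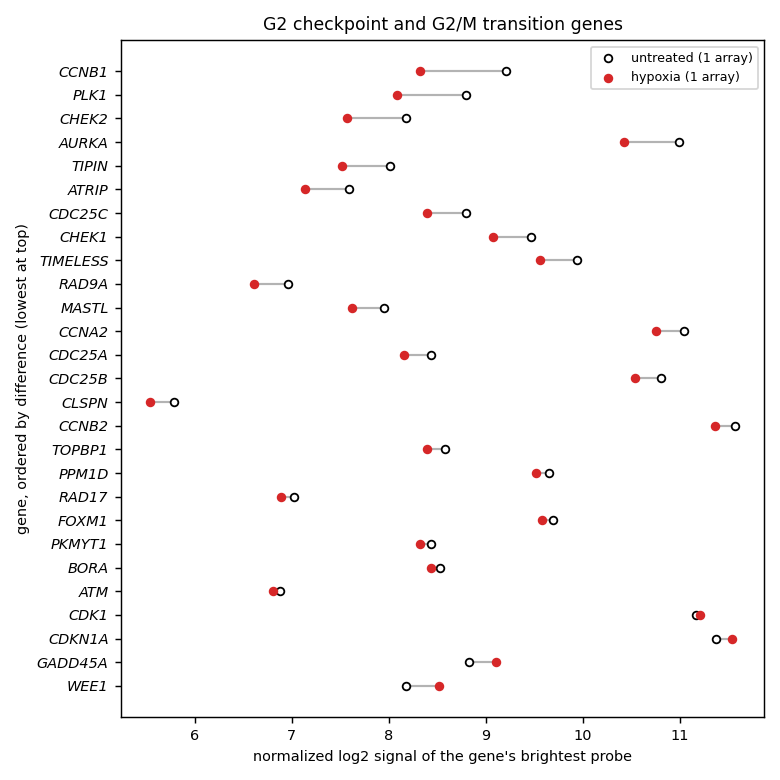
Normalized log2 signal of the brightest probe (horizontal axis) for each measured gene of the G2 checkpoint and G2/M transition list (vertical axis, ordered by difference), with open circles for the untreated array and filled circles for the hypoxia array, 1 array each. CCNB1 had the lowest difference (-0.88) and WEE1 the highest (0.34), and CDK1, near 0, changed sign with the mean over its probes.

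Genes that act in mitosis and in DNA replication were lower as well. All 35 measured members of the mitosis and spindle list were below 0, with a median of -0.34 (percentile 0) and none at 2-fold. The spindle checkpoint kinase BUB1B was at -0.79, CDC20, which activates the anaphase-promoting complex, at -0.67, the spindle protein HMMR at -0.66 and the centrosome kinase NEK2 at -0.65. The G1/S and DNA replication list had 34 of 43 members below 0 and 8 above, a median of -0.23 (percentile 0.14) and none at 2-fold. In it, GINS4, a subunit of the replicative helicase, was at -0.60, the replication initiation factor MCM10 at -0.55 with probes from -0.55 to -0.06, and geminin (GMNN), which restrains origin licensing, at -0.54. RRM2, a subunit of ribonucleotide reductase, was among the 8 above 0, at 0.50. Replication-dependent histone genes had a median of -0.08 over 12 members (percentile 42.8), with the lowest values for H4C8 (-0.31) and H4C3 (-0.29), H4C14 and H2AC6 at -0.19 each, and near-identical family members that probes may not separate.

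DNA repair genes followed the same direction. In the homologous recombination and Fanconi pathway list, 17 of 21 members were below 0, the median was -0.27 (percentile 0.81) and none reached 2-fold. The largest differences were those of FANCE, a subunit of the Fanconi core complex (-0.95), the recombination genes RAD51D (-0.64) and RAD51C (-0.48), and RAD54L, a recombination motor protein (-0.49). In the mismatch and base excision repair list, 14 of 16 members were below 0, with a median of -0.27 (percentile 1.44). The DNA glycosylases NTHL1, UNG and OGG1 were at -0.93, -0.73 and -0.58, and DNA ligase LIG3 at -0.53. The probes of OGG1 ranged from -0.58 to -0.11 and those of LIG3 from -0.53 to -0.04.

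Genes known to be driven by the hypoxia-inducible factors (HIF) had the highest median of the 27 lists. In the core HIF target list, 26 of 28 measured members were at least 2-fold higher, and the median was 2.62 (6.17-fold, percentile 100), or 2.44 with genes of 1 array at their bound. The exceptions, BHLHE41 (0.98) and PFKFB3 (0.31), were named after their values were seen. The collagen cross-linking enzyme LOX was 11.6-fold higher and BNIP3, a mitophagy receptor, 10.05-fold. DDIT4, an inhibitor of mTORC1, was 10.04-fold higher, and PFKFB4, which sets a key activator of glycolysis, 9.99-fold. TMEM45A was 9.88-fold higher on its brightest probe. VEGFA, the main angiogenic growth factor, was 2.21-fold higher.

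Glycolytic genes formed the next highest list, with 11 of 16 members at least 2-fold higher, none lower by that much and a median of 1.39 (2.63-fold, percentile 100). The aldolase ALDOC had the largest difference of all genes detected on both arrays, at 21.3-fold (log2 7.72 to 12.14, probe ILMN_1755974). The enolase ENO2 was 6.17-fold higher, the hexokinase HK2 4.74-fold and phosphoglycerate kinase PGK1 3.84-fold. The 5 members within 2-fold were LDHA (0.85), TPI1 (0.70), ENO1 (0.26), GAPDH (0.13) and PFKM (-0.40), named after their values were seen. GAPDH was among the brightest genes, and its 3 probes gave 0.13, 0.21 and 0.79, the highest difference on the dimmest probe. The tricarboxylic acid cycle list was lower instead, 15 of 18 below 0 with a median of -0.33 (percentile 0.15), including SUCLG1 (-0.44) and SUCLA2 (-0.42). The list also held genes of cytosolic enzymes, among them its lowest member, IDH1 (-0.81). The subunits of the cycle's NAD-dependent isocitrate dehydrogenase were at -0.40 (IDH3A), -0.38 (IDH3B) and 0.18 (IDH3G). Mitochondrial IDH2 was the only member past 2-fold, at 2.36-fold higher. In the oxidative phosphorylation list, 24 of 28 members were below 0, with a median of -0.23 (percentile 0.29) and the lowest values for SDHD (-0.66), ATP5MC1 (-0.64), COX7B (-0.57) and ATP5F1B (-0.54).

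**Figure D2:**
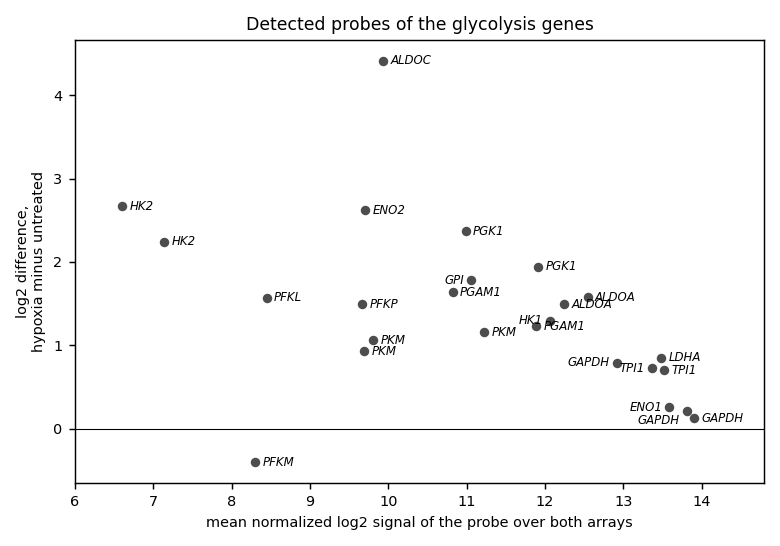
Log2 difference of hypoxia minus untreated (vertical axis) against mean normalized log2 signal over both arrays (horizontal axis) for each detected probe of the glycolysis genes, 1 point per probe. ALDOC lies highest at 4.42, and the 2 brightest probes of GAPDH lie at 0.13 and 0.21.

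The collagen modification and matrix list had a median of 0.60 (percentile 100), with 11 of 17 members above 0 and 6 below. The lowest, COL5A2 (-0.71) and COL3A1 (-0.61), were named after their values were seen. Of the 17, 5 were at least 2-fold higher. Besides LOX these included the lysyl hydroxylase PLOD2 (5.67-fold) and the prolyl hydroxylase subunits P4HA1 (4.23-fold) and P4HA2 (3.26-fold), but LOX, P4HA1 and P4HA2 also belong to the core HIF list. In the list of jumonji demethylases and oxygen sensors, 3 of 13 members passed 2-fold and the median was 0.51 (percentile 99.97), or 0.44 with genes of 1 array at their bound. The HIF prolyl hydroxylase EGLN1 was 4.13-fold higher, EGLN3 at least 3.94-fold (2.61-fold without background correction) and the histone demethylase KDM3A 3.15-fold, while KDM5B was 1.81-fold higher. EGLN1, EGLN3 and KDM3A also belong to the core HIF list. The median of the demethylase list was 0.16, at percentile 95.84, with a detection p under 0.05.

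Ribosome biogenesis and heat shock genes were the lowest lists. Of 23 ribosome biogenesis genes, 20 were below 0, with a median of -0.49 (percentile 0). RRP9, a component of the box C/D particle that processes ribosomal RNA, was 2.24-fold lower and the only member past 2-fold. The nucleolar proteins NOP2, PES1 and RRS1 were at -0.96, -0.91 and -0.91. Of 17 heat shock genes, 14 were below 0, with a median of -0.48 (percentile 0). The small heat shock protein CRYAB was 2.56-fold lower, the chaperones HSPA4 and HSPH1 stood at -0.89 and -0.88, and HSPA1A, nearly identical to HSPA1B, at -0.82. Cytosolic ribosomal protein genes had a median of -0.05 over 30 members (percentile 51.3), which was 0.14 with median centring, so no direction is given. Their largest differences were 0.30 for RPL32, -0.25 for RPL3, 0.22 for RPL4 and -0.20 for RPS15.

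**Figure D3:**
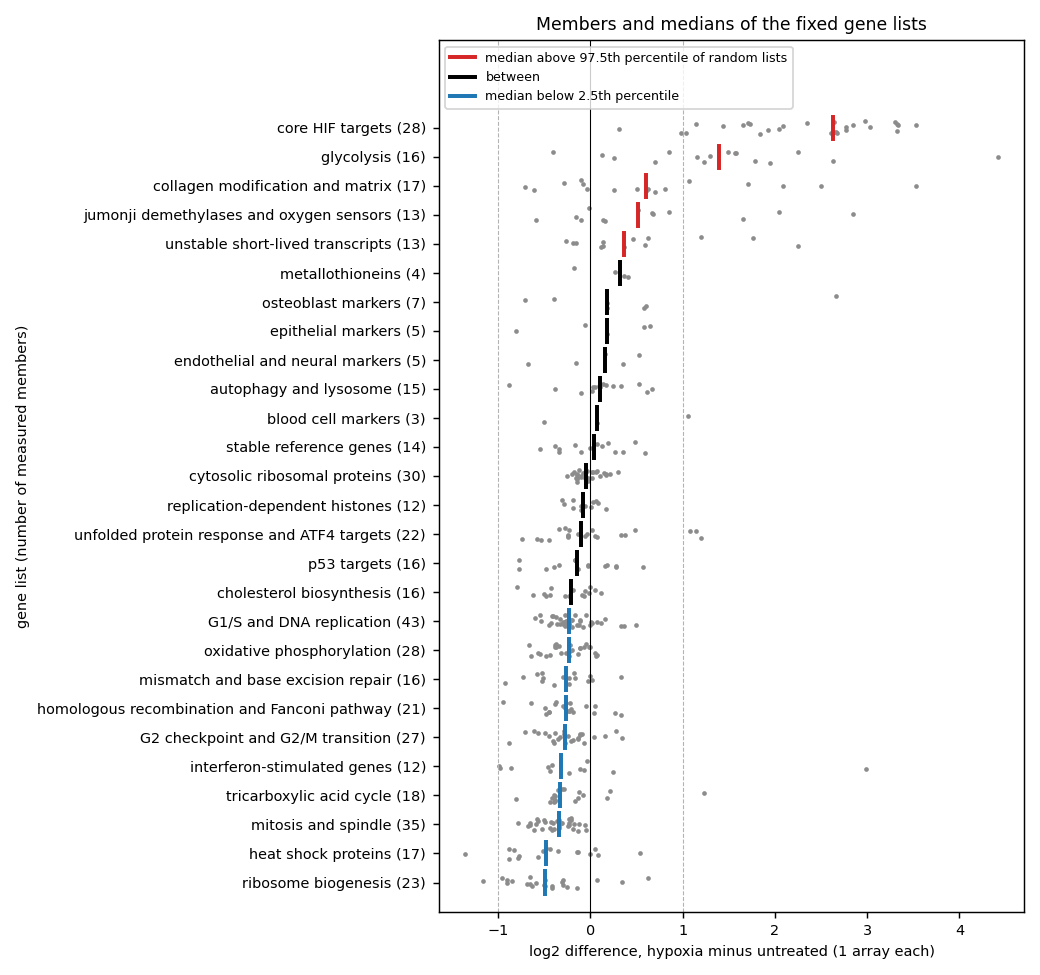
Log2 difference of hypoxia minus untreated, 1 array each (horizontal axis), for each measured member (grey points) of the 27 fixed gene lists (vertical axis, number of measured members in parentheses), with the list median as a bar coloured by its place among 10000 matched random lists. The core HIF list has the highest median (2.62) and ribosome biogenesis the lowest (-0.49), and the medians of ribosomal proteins, stable reference genes and metallothioneins changed sign under at least 1 other setting.

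Transcripts that are made and degraded quickly had a median of 0.37 over 13 members (percentile 99.9). The phosphatase DUSP1 was 4.76-fold higher, the transcription factor JUN 3.40-fold and ATF3, a stress-induced factor, 2.29-fold, whereas MYC was 1.54-fold higher. In the list of the unfolded protein response and ATF4, 3 of 22 members passed 2-fold (ATF3, VEGFA and VLDLR, the last 2.11-fold higher), but 13 were below 0, among them NUPR1 (-0.58), and the median was -0.10 (percentile 31.4). The p53 target list had a median of -0.14 over 16 members (percentile 18.03), none past 2-fold. DDB2 was at 0.56, AEN at -0.48, GDF15 at least 1.45-fold lower and ZMAT3 at -0.77, with probes from -0.77 to 0.38. Of 12 interferon-stimulated genes, 10 were below 0 and the median was -0.32 (percentile 1.15), including IFIT1 (-0.99), IFI44 (-0.86) and ISG15 (-0.46). ISG20, an exonuclease, was 7.95-fold higher. The low place of the interferon list was lost under 6 of the 9 alternative settings.

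The remaining metabolic and reference lists lay within the central 95% of random lists. Cholesterol biosynthesis had a median of -0.21 over 16 members (percentile 5.43), with FDPS at -0.79, HSD17B7 at -0.62, PMVK at -0.50 and LSS at -0.49, whose probes ranged from -0.70 to 0.33. Autophagy and lysosome genes had a median of 0.10 over 15 members (percentile 93.6). In that list GABARAPL1 and ULK1, which act in autophagosome formation, were at 0.67 and 0.61, ATP6V0D1 at 0.53 and the autophagy receptor SQSTM1 at -0.89. The 4 metallothioneins had a median of 0.32 (percentile 97.47), with MT1X at 0.40, MT1G at 0.37, MT2A at 0.27 and MT1E at -0.18. The metallothionein median lay above the central 95% under 4 settings and turned to -0.028 without a detection filter, and the MT1 genes are near-identical. Stable reference genes had a median of 0.03 over 14 members (percentile 83.6), with TFRC at 0.60, HPRT1 at 0.48, ATP5F1B at -0.54 and SDHA at -0.39, and that median changed sign under 3 settings.

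The fixed marker lists of bone, epithelial, blood, endothelial and neural cells lay within the central 95% of random lists in the processing used here. Osteoblast markers had a median of 0.18 over 7 members (percentile 91.0), which lay above the central 95% of random lists under 2 settings. Alkaline phosphatase (ALPL), a marker of bone-forming cells, was 6.32-fold higher, COL1A1 and SPARC were at 0.60 and 0.58, and osteopontin (SPP1) was at least 1.53-fold lower, or 1.28-fold without background correction. Epithelial markers had a median of 0.18 over 5 members (percentile 82.7), with KRT18 at -0.80, KRT14 at 0.65, EPCAM at 0.18 and KRT8 at -0.06. Blood cell markers had a median of 0.07 over 3 members (percentile 59.9), with CORO1A at -0.51 and CD68 at 1.06, although its probes ranged from -0.01 to 1.06. That median is the value of LYZ, which was detected on the hypoxia array only and has no usable bound. Endothelial and neural markers had a median of 0.16 over 5 members (percentile 84.1), with OLIG2 at -0.68, SNAP25 at 0.53, TUBB3 at 0.36 and TEK at -0.15. That median is the value of PECAM1, detected on the hypoxia array only, and was 0.15 with PECAM1 at its bound.

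Outside the lists, the genes with the largest differences were of several kinds. UPK1A, a membrane protein of the bladder lining, was 20.1-fold higher, and SYTL2, an effector in vesicle transport, 14.1-fold, with probes from 0.56 to 3.82. The secreted glycoprotein STC1 was 13.49-fold higher, MAP3K7CL 10.9-fold, BEND5 9.75-fold and PPP1R3C, which targets a phosphatase to glycogen, 9.13-fold. On the untreated array BEND5 lay close to the detection limit (log2 5.54 against 5.52), and MAP3K7CL, STC1, UPK1A and SYTL2 lay at 5.96 to 6.35. The folds of such dim probes depend on the background correction. NPPB, the B-type natriuretic peptide, was detected on the hypoxia array only and was at least 58.6-fold higher there (probe ILMN_1763382). The protease KLK4 was at least 15.0-fold higher and ZP1, an egg coat protein, at least 8.49-fold. KRTAP2-4 (at least 10.3-fold) and HCG4 (at least 9.02-fold) belong to families of close paralogs, so the source gene is uncertain. Without background correction, the bounds of NPPB, KLK4, KRTAP2-4, HCG4 and ZP1 were 32.6-fold, 8.67-fold, 6.10-fold, 5.40-fold and 5.11-fold.

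Among the genes with the lowest differences, PRDM1, a transcriptional repressor, was 4.75-fold lower, DYNC1I1, a dynein chain, 3.81-fold and CD70, a ligand of the tumour necrosis factor family, 3.48-fold. The transglutaminase TGM2 was 3.39-fold lower, MLKL, the effector of necroptosis, 3.33-fold, the potassium channel KCNJ8 3.31-fold and thrombospondin THBS1 3.30-fold. The chemokine CX3CL1 was 3.17-fold lower, RASL11B 3.09-fold, the kinase SGK1 2.86-fold and CCN3, a matricellular protein, 2.78-fold. SOX2, a stem cell transcription factor, was detected on the untreated array only and was at least 6.88-fold lower in hypoxia. SOSTDC1, LGR4 and ROR1, which act in Wnt signalling, were at least 3.68-fold, 2.96-fold and 2.80-fold lower, and PARM1 at least 2.51-fold. Without background correction, the bounds were 4.11-fold for SOX2, 2.42-fold for SOSTDC1 and 2.04-fold for LGR4, while ROR1 (1.95-fold) and PARM1 (1.80-fold) no longer passed 2-fold. No direction of these named genes turned under the alternatives, apart from CDK1 and PKMYT1.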

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

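The tests of explanations in this part were chosen after the results were seen. A signal in data outside the report came from probes with no single listed gene. Of 21225 such probes, 2075 were detected on at least 1 array, 69 were at least 2-fold higher on the hypoxia array and 11 at least 2-fold lower. Of the 69, 13 were detected on the hypoxia array only, and the differences or bounds reached 6.90 and -1.52. The shares past 2-fold were close to those of the measured genes, of which 295 were higher and 63 lower out of 9558. These probes were singled out only because no comparison above uses them, and their genes were not analysed here.

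Genes past 2-fold were mostly higher in hypoxia, 295 against 63 (82.4% higher). The choice between quantile normalization and median centring is argued against as the whole cause. Median centring moved other results, such as the heat shock median to -0.34, and left 82.7% higher (297 against 62, 95% Wilson interval 78.5% to 86.3%). A larger scaling error was not tested. Median centring moved the median of all genes only from -0.06 to -0.04, while a common shift of 0.24 would balance the counts. Both scalings assume that most genes do not differ between the arrays. The authors' values gave 235 against 38, but they look quantile normalized as well and are no separate test of scaling. Compression of low signals near background is argued against as the whole cause, since among 4304 genes at a mean level of 8 or more the share was 86.4% (127 against 20, 79.9% to 91.0%, with genes treated as independent and counting error only). The hypoxia exposure itself remains open and untested, because with 1 array per group an effect of the array or culture cannot be told apart from it.

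On their brightest probes, GAPDH (0.13) and ENO1 (0.26) differed far less than the median of the glycolysis list (1.39). Compression of very bright signals may contribute, since in 9 genes with a very bright probe (level 13 or more) and a dimmer second probe that differed by at least 0.3, the bright probe showed a median of 37.7% of the second probe's difference (bootstrap 95% interval -22.5% to 63.9%), against 76.1% in 294 genes of middle level chosen with the same limit of 0.3, which lowers the share in both sets. Quantile normalization at the top of the range is argued against as the whole cause, since with median centring the mean of GAPDH and ENO1 was 25.8% of the list's median (0.37 against 1.45). The test of bright probes used 2 probes per gene, and the 2 brightest of GAPDH both lie above level 13. The third GAPDH probe, at level 12.91, differed by 0.79, against 0.13 and 0.21 on the brighter 2. That order goes with compression in GAPDH. It rests on 1 probe close to level 13, so the size of any compression was not measured. Among the 9 genes, ITIH5, whose second probe lay near the detection limit, and RPL10A had probes of opposite sign, which compression alone does not give. Before background correction, ENO1 had an untreated signal of 10799.5, above TPI1 (8783 and 7909) and LDHA (8166). In hypoxia ENO1 (14221) lay below TPI1 (15729 and 14520) and LDHA (15954), whose differences were 0.70, 0.73 and 0.85. Compression that follows 1 curve for all probes does not reverse such an order, so these values argue against that form as the whole cause for ENO1. Compression that differs from probe to probe could reverse it, was not tested and stays open for ENO1. The brightest GAPDH probes (16363 and 16033) stayed above those of TPI1 and LDHA, so compression of either form remains open for GAPDH. A smaller response of GAPDH and ENO1 to hypoxia stays open and untested.

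The mitosis, G2 checkpoint and replication lists were all lower, by -0.34, -0.28 and -0.23 in the median. For the mitosis list, a trend of the difference with signal level is argued against as the whole cause. Its median was still -0.28 after a running median over level was removed. The G2 and replication medians stayed below 0, at -0.19 and -0.16, but the limit of this test was set for the mitosis list only. A common lower level of all cell cycle transcripts stays open by its test, since the replication and mitosis medians differed by 0.11, or 1.32 SDs of the difference between matched random lists. The replication-dependent histones (median -0.08, percentile 42.8) and RRM2 (0.50), UHRF1 (0.37) and TK1 (0.33) did not share the lower level. They do not decide against an equal shift of every such transcript. RRM2, UHRF1 and TK1 are the highest members of the replication list, picked for their values. Most histone transcripts lack the poly(A) tail on which labelling usually relies. An effect of hypoxia on these genes and one of the array or culture remain open.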

How the results depend on the processing

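All alternatives in this part were planned, except those for GAPDH and ENO1, which were added after their values were seen. No list outside the central 95% of random lists and no named gene past 2-fold changed sign, while the medians of ribosomal proteins, metallothioneins and stable reference genes and the values of CDK1 and PKMYT1, all near 0 or within that range, did under at least 1 setting. The counts of higher genes stayed within 1.5 times the 295 reported (205 to 372). The count of genes at least 2-fold lower was 30 without background correction, 30 with an offset of 50, 124 with an offset of 1 and 38 with the authors' value table, in place of 63. Of the genes higher and lower in the authors' table, 233 and 38 were shared with those reported. Without background correction, the medians were 2.14 for core HIF targets, 0.30 for jumonji demethylases and -0.19 for interferon-stimulated genes. With an offset of 50, they were 2.14 for core HIF targets and 0.31 for jumonji demethylases, and an offset of 1 gave 0.69 for the latter. Median centring gave -0.17 for oxidative phosphorylation, 0.14 for ribosomal proteins, -0.34 for heat shock proteins and 0.16 for stable reference genes. Detection on both arrays gave 2.48 for core HIF targets and 0.38 for osteoblast markers. A detection p under 0.05 gave 2.48 for core HIF targets, 0.16 for jumonji demethylases, -0.15 for interferon-stimulated genes and 0.25 for short-lived transcripts. Without a detection filter, medians were 2.35 for core HIF targets, 0.47 for collagen modification, 0.14 for jumonji demethylases, -0.12 for interferon-stimulated genes, -0.028 for metallothioneins and 0.25 for short-lived transcripts. For core HIF targets, the mean over probes gave 2.40 and the authors' values gave 2.25, and the authors' values gave 0.33 for jumonji demethylases. Higher offsets and no background correction shrink differences of dim probes by their construction, and for the other settings the cause was not tested. The G2 checkpoint median stayed between -0.29 and -0.21, below the 2.5th percentile under all 9 settings (0.17 to 2.45). Of the 27 lists, 4 changed their place relative to the central 95% of random lists under at least 1 setting, and unmatched random lists moved none. Between 99 and 142 of 142 named genes, GAPDH and ENO1 included, stayed within 1 between-probe SD under 8 of the settings, and detection on both arrays measured 129 of them. Signal over background limits the dim genes most, since a gene detected on 1 array has only a bound.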

Other observations

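The 3 gene lists in this part, and their tests, were chosen after the genes past 2-fold and some genes within 2-fold were seen. The prompting members within 2-fold were PYGL, SQSTM1, MGST1 and SLC7A11. Each list was tested on the members that had not prompted it. Genes of glycogen metabolism stood among the higher genes. PPP1R3C was 9.13-fold higher, glycogen synthase GYS1 5.11-fold, the branching enzyme GBE1 4.47-fold and phosphoglucomutase PGM1 3.50-fold, while the phosphorylase PYGL was at 0.997. All 18 measured members had a median of 0.23 (percentile 99.4 of matched random lists), and the 13 that had not prompted the list one of 0.01 (percentile 69.6), with 7 above 0 and 6 below. Whether the set as a whole is higher stays open, since the prompting members were picked for their high values and the rest is biased towards no difference.

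Several targets of NRF2, the regulator of the antioxidant response, had differences below 0, but only 1 of 19 measured was at least 2-fold lower. NQO1, a quinone reductase, was 2.17-fold lower, SQSTM1 was at -0.89, MGST1 at -0.88 and the cystine transporter SLC7A11 at -0.45. Of 15 other measured targets 11 were below 0, among them the thioredoxin reductase TXNRD1 (-0.81), PIR (-0.67) and GCLM (-0.61), and HMOX1 was at 0.01. All 19 measured targets had a median of -0.40 (percentile 0.01), which includes the members picked for their low values. The other 15 had one of -0.23 at percentile 4.07, near the limit of 2.5 set for the test, so a lower level of the set was neither shown nor excluded.

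Of 14 measured genes typical of skeletal muscle, the 8 that prompted the list were at least 2-fold higher in hypoxia. The acetylcholine receptor subunit CHRNA1 was at least 5.63-fold higher and CHRNB1 4.70-fold, JSRP1 at least 5.95-fold and sarcolipin (SLN) 4.94-fold. The cadherin CDH15 was 3.91-fold higher, KLHL41 at least 3.00-fold, the muscle regulator MYOD1 at least 2.74-fold and TNNT1 2.24-fold. CHRNA1, JSRP1, KLHL41 and MYOD1 were detected on the hypoxia array only. Whether their bounds pass 2-fold without background correction is not given here. The 6 other measured members had a median of 0.44 (percentile 99.4), 5 above 0 and none past 2-fold, from RYR1 (0.95) to MUSK (-0.21). It may be that part of a muscle gene set is higher in these hypoxic cells, as a hypothesis found and tested on the same arrays. Of the 36 listed genes, 22 were detected on neither array, among them the abundant muscle transcripts ACTA1, CKM, DES and TTN.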
